A study of Mus musculus with 12 samples.

How the data were processed

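RNA-seq libraries came from mouse embryos (CB6F1/J, E12.5) carrying the Hb9:GFP reporter. Per the labels, ventral spinal cord tissue from pooled embryos was dissociated with papain and sorted by GFP, RNA was purified on columns with DNase, and polyA-selected libraries were made with a kit that does not keep strand and read as 50-base single ends. The deposited tables hold 12 libraries: 5 control and 5 Arhgap35 knockout libraries of GFP-positive cells, and 1 of each genotype of GFP-negative cells. The labels call GFP-negative samples motor neurons too; they were grouped by their GFP status. Columns were matched to samples by genotype, sort and replicate number, and 0 columns were left unmatched.

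The authors deposited a table of estimated counts (expected counts per gene symbol, not normalized between libraries), of which 39.2% are exactly whole, zeros included, and a table of TPM (transcripts-per-million values). The labels name kallisto, without a version, and the mm10 genome; how transcripts were summed to symbols is not given in the sources used here. The TPM columns sum to different totals, from 974800 to 1018240, so the deposited TPM were rescaled between libraries in a way the labels do not state, and 1522 TPM values lie above 0 where the estimated count is listed at 0. All comparisons rest on the estimated counts, rounded to whole numbers, and TPM served as an alternative. The tables hold 30740 symbols, of which 27027 were given 1 position on GRCm38 from GENCODE M21 (25742), RefSeq (267) or synonyms (1018), and 3713 had none.

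Total estimated counts were 23.7 to 30.2 M in control and 24.6 to 33.8 M in knockout GFP-positive libraries, and 28.7 and 26.5 M in the control and knockout GFP-negative libraries. A floor of 3 counts corresponds to 0.0887 to 0.127 CPM, by library. Within a group, pairs of replicates correlated at r of 0.973 to 0.985, and none were duplicates (chi-square per degree of freedom of 8.59 to 26.6). Levels are CPM with TMM-scaled library sizes, as mean and SD over libraries.

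Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR's robust quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 values from the edgeR fit at its default prior count, with standard errors and 95% confidence intervals. A prior count of 2 entered log2 CPM values, not these fold changes. Knockout was compared with control in the 10 GFP-positive libraries (17487 genes), GFP-positive with GFP-negative cells in all 12 with genotype as a covariate (19763 genes), and the knockout effect in GFP-negative minus that in GFP-positive cells in a fit with 4 group means. In the last, each lone GFP-negative library is assumed to vary like the replicated groups. Genes with 0 counts in a group are given as lower bounds against the floor, and those with 1 to 3 counts as ratios with a counting interval.

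A set of 38 gene lists was fixed before the data were examined and tested with camera at its preset correlation of 0.01, with BH adjustment over the lists, and again with camera at an estimated correlation and with fry. Lists needed at least 3 measured genes. Adjustment over the list alone means BH over the genes of 1 list. List levels per library, as mean log2 CPM, and technical measures were compared by two-sided exact permutation of 5 against 5 libraries, whose smallest p is 0.00794.

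Replicate numbers were checked for pairing on residuals from the group means. Libraries of the same number correlated at r = 0.381, 0.252, 0.179, 0.277 and 0.310, against at most 0.104 for other pairs, and each library's best partner carried its own number, so a fit with the replicate number as a block was run beside the unblocked one. What the numbers share (a litter, a day) is not given in the sources used here.

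The genes named were set by a rule written before the data were examined: Arhgap35; the 10 largest fold changes per direction among called genes with an average log2 CPM of at least 1 whose groups do not overlap, unnamed gene models left out; from each list up to 4 called members with the smallest p, or 2 where none was called; and up to 5 interaction genes per direction, or the 3 with the smallest p. Fewer members are named where lists share them, and some of the lists and genes that were tested are not given in the text or plotted. Grlf1, Akt2-ps, Akt2, 9330104G04Rik, AK035387, Bcam, other neighbours of Arhgap35 and the 5 unnamed interaction genes fall outside the rule and were chosen after their values were seen.

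Alternatives were other scaling (DESeq2 size factors, upper quartile, library size only), no filter or a CPM of at least 1 in 5 libraries, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1 (mean TPM of at least 1, or no filter), robust fitting off, all 12 libraries together, the replicate block, 1 surrogate variable (sva 3.50.0), either genotype alone, no genotype term, leaving out genes within 20 Mb of Arhgap35, and leaving out each library in turn. The 10 GFP-positive libraries were also divided into other groups of 5 and 5, as 100 of the possible splits, the real one included.

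The procedure was tested on simulated data with 50 genes changed at each of several sizes. For knockout against control it recovered most genes changed by 2-fold and a smaller part of those changed by 1.5-fold. The interaction recovered fewer, having 1 GFP-negative library per genotype. The simulated counts held no shared effect of the replicate number, so recovery in the real libraries may differ. Isoforms, reads and variants were not analysed here, since the deposited tables hold gene-level values only.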

Results

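RNA was sequenced from cells of the embryonic mouse spinal cord that had been sorted by flow cytometry on the Hb9:GFP reporter, a transgene that labels spinal motor neurons through the promoter of Mnx1 (also called Hb9). Ventral cord tissue at E12.5 (embryonic days) came from embryos lacking Arhgap35, which encodes the protein p190, and from littermate controls, which the protocol describes as wild-type or heterozygous. Cells were pooled and sorted into 5 control and 5 knockout libraries of GFP-positive cells, with 1 control and 1 knockout library of GFP-negative cells. Total estimated counts ran from 23.7 to 33.8 M per library, 24098 to 24947 genes had at least 1 count, and mitochondrial transcripts took 1.03 to 1.68% of the counts. Library totals were 25.2 ± 2.85 M in control and 27.6 ± 4.00 M in knockout GFP-positive cells (SD, n = 5 each; two-sided exact permutation p = 0.206, adjusted p = 0.516 over 5 technical measures). The labels do not say that the replicates came from separate litters, so p-values measure the spread between these libraries.

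Arhgap35, the targeted gene (chromosome 7, 16493719 to 16614993, GRCm38), was lower in every knockout library than in every control library of GFP-positive cells. Its counts-per-million level (CPM) was 173 ± 25.6 CPM in control and 96.9 ± 7.84 CPM in knockout cells (SD, n = 5 each), a log2 fold change of -0.83 with a standard error of 0.0996 and a 95% confidence interval of -1.05 to -0.61. The difference passed edgeR's quasi-likelihood test (adjusted p = 0.0240), but not with the replicate number as a block (log2 fold change -0.82, adjusted p = 0.162). Leaving out 1 library at a time gave adjusted p of 0.000758 to 0.141, and the call held only without control replicate 5, while the log2 fold change stayed between -0.91 and -0.77. In GFP-negative cells Arhgap35 stood at 155 CPM in the control and 96.4 CPM in the knockout library. The deposited tables carry an older symbol of the same gene, Grlf1, as a separate entry. Grlf1 stood at 48.7 ± 20.5 CPM in control and 6.21 ± 3.50 CPM in knockout cells (SD, n = 5 each) and was lower in all 5 knockout libraries, but it missed the threshold (log2 fold change -2.96, edgeR adjusted p = 0.9999). Summed as 1 gene, a choice made after the values were seen, both entries gave a log2 fold change of -1.10 and passed edgeR's threshold. Which part of Arhgap35 was deleted is not given in the sources used here, so reads from outside that part cannot test the genotype.

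**Figure D1:**
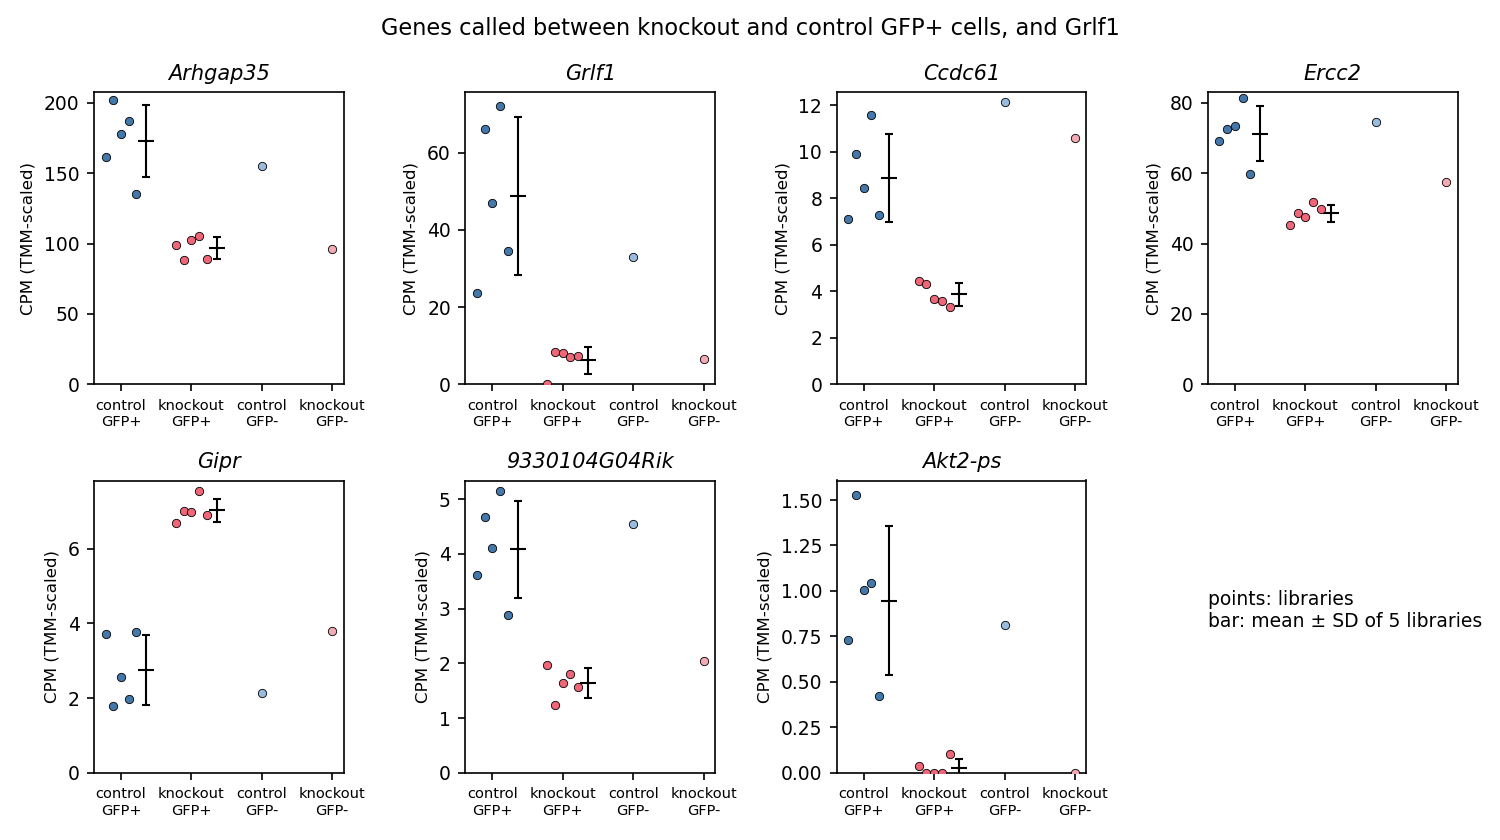
Expression in CPM (y axis, linear, TMM-scaled) of the 6 genes called between knockout and control GFP-positive cells and of Grlf1, with 1 point per library and bars for the mean and SD of 5 libraries; the GFP-negative groups have 1 library each. In GFP-positive cells the 5 knockout libraries lie apart from the 5 control libraries for every gene plotted, below them for all but Gipr.

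The comparison of knockout with control GFP-positive cells asks what loss of Arhgap35 changes in the transcriptome of motor neurons. Of 17487 genes tested, 1 was higher and 5 were lower in knockout cells, and 4 of the 6 were neighbours of Arhgap35 on chromosome 7. Gipr, which encodes the receptor for the gut hormone GIP (chromosome 7, 19156061 to 19166127), rose from 2.76 ± 0.941 to 7.03 ± 0.311 CPM (SD, n = 5 each; log2 fold change 1.34, standard error 0.194, edgeR adjusted p = 0.0454). Ccdc61, which encodes a coiled-coil protein (chromosome 7, 18890883 to 18910415), fell from 8.87 ± 1.88 to 3.87 ± 0.498 CPM (SD, n = 5 each; log2 fold change -1.20, standard error 0.148, edgeR adjusted p = 0.0240). Ercc2, which encodes a DNA helicase of transcription factor TFIIH (chromosome 7, 19382010 to 19395694), fell from 71.3 ± 7.78 to 48.6 ± 2.44 CPM (SD, n = 5 each; log2 fold change -0.55, standard error 0.0705, edgeR adjusted p = 0.0240). Exons of Ercc2 share 744 bp with Klc3 and 1025 bp with the antisense gene Gm26852, and the library kit does not keep strand, so reads within the shared bases cannot be told apart by strand. Klc3 had a log2 fold change of 0.76.

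The other called genes were a long noncoding RNA and a pseudogene, named here after their values were seen. The noncoding RNA 9330104G04Rik (chromosome 7, 16871347 to 16874886) fell from 4.08 ± 0.887 to 1.65 ± 0.276 CPM (SD, n = 5 each; log2 fold change -1.31, edgeR adjusted p = 0.0309). Akt2-ps, a processed pseudogene (chromosome 11, 16514533 to 16515981), stood at 0.947 ± 0.411 CPM in control and 0.0284 ± 0.0449 CPM in knockout cells (SD, n = 5 each; edgeR adjusted p = 0.0240), with 10 to 36 counts in each control and 0 to 3 in each knockout library. Of its 31-base sequences, 67.9% also occur in Akt2, which lies on chromosome 7, 10.98 Mb from Arhgap35, so its reads are hard to place. Akt2 itself stood at 56.6 ± 3.74 CPM in control and 55.9 ± 2.48 CPM in knockout cells (SD, n = 5 each; log2 fold change -0.020, edgeR adjusted p = 0.9999). With the replicate number as a block 5 genes were called: Ccdc61, Ercc2 and 9330104G04Rik, with Bcam and AK035387 in place of the other 3. Under the block Gipr had an edgeR adjusted p of 0.0965 and Akt2-ps 0.0871, while Bcam (log2 fold change 0.48, chromosome 7, 19756131 to 19771016) and AK035387 (log2 fold change 0.60) had 0.0190 each. DESeq2 called 14 genes, including these 6, and voom 5. No gene was called when control replicates 2, 3 or 4 or knockout replicates 1, 3 or 4 were left out. Without knockout replicate 2 edgeR called 2 genes, neither among these 6, and without knockout replicate 5 it called 1 of the 6. Without control replicates 1 and 5 it called 6 and 8 genes, 5 and 6 of them among the 6.

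Differences between the genotypes clustered around Arhgap35. Within 20 Mb of it, 31 of 407 tested genes (7.62%, Arhgap35 and Grlf1 left out) had an unadjusted edgeR p under 0.01. Elsewhere 30 of 15560 placed genes did (0.193%, one-sided Fisher's exact test, p = 1.47e-33). Evenly spread p-values would give a share of 0.01, so the low share elsewhere enlarges the contrast. Fisher's test counts genes as separate units, though all come from the same 10 libraries, so its p does not measure spread between libraries. By distance, the share was 21 of 106 genes up to 5 Mb away, 0 of 63 from 5 to 10 Mb, 7 of 211 from 10 to 15 Mb and 3 of 27 from 15 to 20 Mb. Pnmal2 (log2 fold change 0.47), Trappc6a (0.65) and Sae1 (0.19) were among those with higher means in knockout cells, and Npas1 (-0.87), Zfp128 (-0.49) and Mark4 (-0.17) among those with lower means. None of these 6 passed the adjusted threshold, and they were named after their values were seen. Genes called outside this window numbered 1, Akt2-ps.

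**Figure D2:**
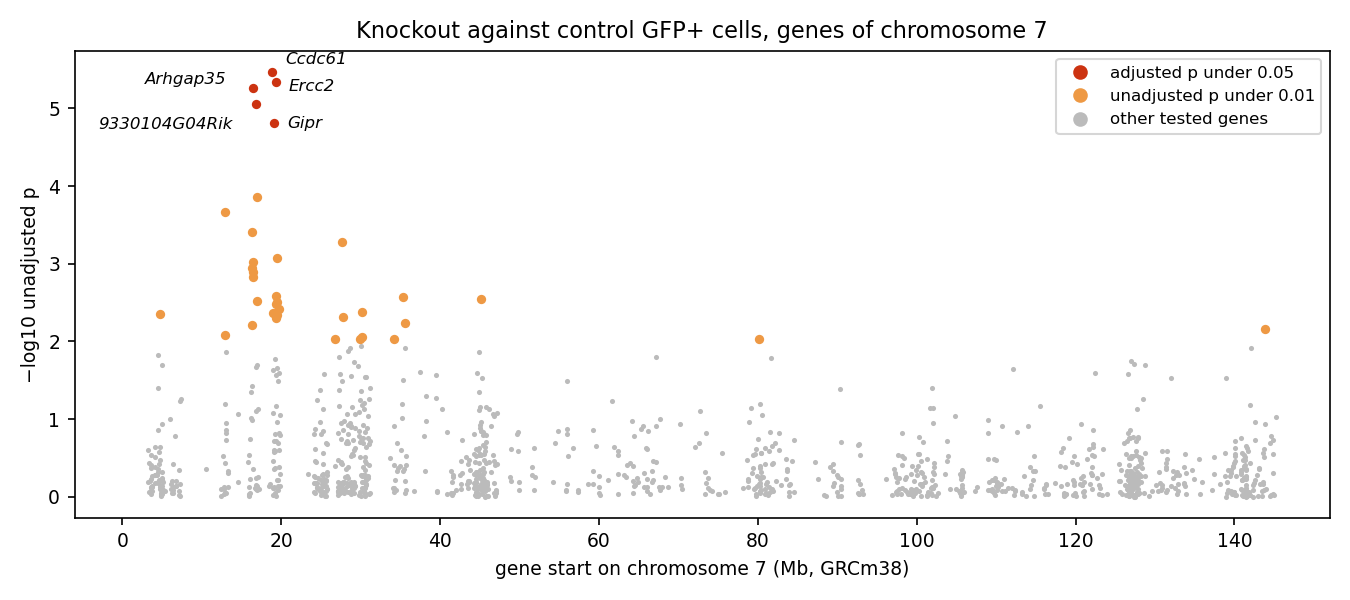
Genes of chromosome 7 by start position (x axis, Mb, GRCm38) and by the -log10 of their unadjusted edgeR p between knockout and control GFP-positive cells (y axis). Points in red are the 5 called genes on the chromosome, and orange points are other genes with an unadjusted p under 0.01; 34 of 1208 tested genes of the chromosome had such a p, most of them within 20 Mb of Arhgap35.

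For the rest of the transcriptome the libraries allowed narrow limits. Among 10676 genes with an average log2 CPM of at least 3, the 95% confidence interval of the log2 fold change lay within 1.5-fold of no change for 97.6% and within 2-fold for 98.97%, with a median distance of 0.124 from the estimate to its limits. Across all genes 375 had an unadjusted p under 0.05, and 889 with the replicate block. Evenly spread p-values would put a share of 0.05 of the 17487 genes there. The count with the block lies close to that share and the count without it far below, so neither shows an excess. The fit without the block leaves the pairing by replicate number in its spread (median standard error 0.0877, against 0.0650 with the block). Its low count therefore cannot show that an excess is absent. Without regard to pairs, 0.515% of genes kept their 5 knockout libraries wholly apart from the 5 control libraries, where chance gives 0.794%.

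None of the 38 gene lists held a gene called between the genotypes, over all genes or adjusted over the list alone, and each list gene named below had an edgeR adjusted p of 0.9999. At an unadjusted p under 0.05 stood 12 cholesterol synthesis genes and 0 to 3 genes of each other list. Motor neuron identity genes stayed near their control level in their median (21 measured, median log2 fold change 0.037, mean -0.018, test direction up, camera adjusted p = 0.283). Among them, Nkx6-1, a transcription factor of motor neuron progenitors, had a log2 fold change of 0.11 and Tbx20, below 1 CPM on average in both genotypes, one of -0.83. Motor column and pool markers had a median of 0.047 over 26 genes (camera adjusted p = 0.108, 0.0400 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Nos1 at -0.27 and the cadherin Cdh20 at 0.16. Rostral Hox genes had a median of 0.031 over 11 genes (camera adjusted p = 0.177), with Hoxa7 at 0.14 and Hoxc5 at 0.18.

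No gene of the axon guidance lists was called between the genotypes, and the list medians lay near 0. Single genes were bounded less tightly. In the Slit and Robo list their log2 fold changes ran from -0.74 to 0.31, with 95% confidence intervals reaching -2.85 and 1.37. The netrin, DCC and UNC5 list had a median log2 fold change of 0.010 over 19 genes (camera adjusted p = 0.184), with Ntn3 at 0.12 and the exchange factor Trio at 0.10. Slit and Robo genes had a median of 0.023 over 14 genes and a mean of -0.015 (test direction up, camera adjusted p = 0.283), with Ndfip1 at 0.037 and Ndfip2 at 0.029. Semaphorins, plexins and neuropilins had a median of 0.021 over 30 genes (camera adjusted p = 0.297), with Plxna4 at 0.15 and Sema4b at -0.12, both at an unadjusted p under 0.05. Ephrins and Eph receptors had a median of -0.0060 over 21 genes (camera adjusted p = 0.283), with Ephb1 at -0.10 and Epha10 at -0.097. Cues of motor axon exit and growth had a median of -0.013 over 20 genes (camera adjusted p = 0.689), with Kitl at -0.17 and the receptor Cntfr at 0.042. Neuronal adhesion molecules had a median of 0.032 over 29 genes (camera adjusted p = 0.0535, 0.00609 with the replicate block; adjusted p = 0.471 with the block and an estimated correlation), with Cdh6 at 0.069. Neurofilament, tubulin and axon growth genes had a median of 0.016 over 30 genes (camera adjusted p = 0.0832, 0.00290 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Klf7 at 0.12 and Stmn4 at 0.075.

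Lists of signalling targets had medians near 0 too, with no gene called. YAP and TAZ targets had a median log2 fold change of 0.038 over 17 genes (camera adjusted p = 0.254), with Tead1 at 0.12 and Wwc1 at 0.073. Ras and MAPK feedback genes had a median of 0.032 over 19 genes (camera adjusted p = 0.708), with Myc at -0.13 and Spry2 at 0.093.

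With camera at its preset correlation 7 lists were called, all with small shifts, and none of them kept its call with an estimated correlation. That setting also called 0 lists between GFP-positive and GFP-negative cells, where all 34 proliferation genes were lower. A call lost under it therefore does not argue against a shift of the list. Cholesterol synthesis genes had a median log2 fold change of 0.14 over 24 genes, with 12 at an unadjusted p under 0.05 (camera adjusted p = 3.45e-14, or 0.438 with an estimated correlation). Their library levels overlapped, at 6.08 to 6.24 mean log2 CPM in control and 6.13 to 6.36 in knockout cells (exact permutation p = 0.0714). Knockout replicate 2 was the highest. The knockout library was above the control of the same number in replicates 2, 3 and 4 and below it in 1 and 5. Dhcr7, the last enzyme of the pathway, stood at 87.2 ± 4.35 CPM in control and 98.2 ± 7.32 CPM in knockout cells, and Hmgcs1 at 876 ± 48.4 and 985.7 ± 71.2 CPM (SD, n = 5 each). Glycolysis and hypoxia genes had a median of 0.087 over 29 genes (camera adjusted p = 2.83e-06; adjusted p = 0.638 with an estimated correlation), with Pgk1 at 0.14 and Bnip3 at 0.21. Knockout replicate 2 had the highest level (6.04 mean log2 CPM, other knockout libraries 5.69 to 5.92), and without it the camera adjusted p was 0.0167. The same library was highest for sensory (2.18, other knockout libraries 1.08 to 1.45) and endothelial genes (0.122, other knockout libraries -1.15 to -0.269). The p53 and apoptosis list had a median of 0.074 over 21 genes (camera adjusted p = 4.81e-05; adjusted p = 0.282 with an estimated correlation), with Sesn2 at 0.18 and Bbc3, which lies on chromosome 7 next to Arhgap35, at 0.18. With the replicate block fry called this list as well (adjusted p = 0.00383, against 0.547 without the block). SRF and MRTF targets, which respond to actin, had a median of 0.054 over 29 genes (camera adjusted p = 0.00305; adjusted p = 0.282 with an estimated correlation), with Cnn2 at 0.61 and Csrp1 at 0.26. Knockout replicate 2 had the highest level of this list as well (4.55 mean log2 CPM, other knockout libraries 4.33 to 4.43), and without it the camera adjusted p was 0.0167. Synapse and excitability genes had a median of 0.020 over 47 genes (camera adjusted p = 0.0108; adjusted p = 0.789 with an estimated correlation), with Kcna1 at 0.28. That call ended without control replicate 1, where the list's direction reversed (camera adjusted p = 0.816), and without knockout replicate 5 (0.234). Caudal Hox genes were lower, with a median of -0.14 over 16 genes (camera adjusted p = 0.0143; adjusted p = 0.638 with an estimated correlation), and the call ended without control replicate 1 (0.784) or knockout replicate 5 (0.234). Hoxd9 stood at -0.15 and Hoxc8 at 0.13.

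Markers of other cell types that the sort could have carried along were tested in the same way. Endothelial genes were higher, with a median log2 fold change of 0.31 over 14 genes (camera adjusted p = 0.0105; adjusted p = 0.638 with an estimated correlation). The call ended without control replicate 4 (camera adjusted p = 0.154) or knockout replicates 2 (0.215) or 5 (0.101). Cldn5, a tight junction gene, stood at 0.512 ± 0.208 CPM in control and 1.01 ± 0.502 CPM in knockout cells (SD, n = 5 each), and the receptor Kdr at 1.09 ± 0.463 and 2.63 ± 2.55 CPM (SD, n = 5 each). Mesenchyme, meninges and pericyte genes had a median of 0.11 over 19 genes (camera adjusted p = 0.177, 0.0101 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Col3a1 at 1.68 and Col1a2 at 0.73. Knockout replicate 2 had the highest level of this list (2.05 mean log2 CPM, other knockout libraries 0.942 to 1.58). Erythroid genes had a median of 0.65 over 6 genes (camera adjusted p = 0.184, 0.000739 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Hbb-bs at 1.15 and Hba-a2 at 0.78. Knockout replicate 2 was the highest here too (1.09 mean log2 CPM, other knockout libraries -1.39 to 0.611, control libraries -1.22 to -0.0294), so these higher means rest largely on that library. Ventral interneuron markers had a median of -0.42 over 25 genes (camera adjusted p = 0.184, 1.68e-12 with the replicate block; adjusted p = 0.314 with the block and an estimated correlation), with Dbx1 at -1.08. Dorsal interneuron markers had a median of -0.25 over 19 genes (camera adjusted p = 0.805, 0.0154 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Foxd3 at -0.25 and Prrxl1 at 0.41. Immediate early and dissociation stress genes had a median of -0.045 over 24 genes (camera adjusted p = 0.148, 0.00131 with the replicate block; adjusted p = 0.423 with the block and an estimated correlation), with Npas4 at -0.37 and Fosb, which lies among the neighbours of Arhgap35, at -1.03. With an estimated correlation no list was called under the block either (smallest adjusted p = 0.147, for the p53 list).

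The remaining lists were not called by camera with or without the block. Sensory neuron markers had a median log2 fold change of 0.13 over 15 genes (camera adjusted p = 0.107), with P2rx3 at 0.42. Neural progenitor genes had a median of 0.024 over 24 genes (camera adjusted p = 0.651), with Vim at 0.079 and Cdon at 0.074. Proliferation genes had a median of 0.0043 over 34 genes and a mean of -0.019 (test direction down, camera adjusted p = 0.651), with Mcm5 at -0.16 and Plk1 at -0.31. Floor plate markers had a median of -0.034 over 8 genes (camera adjusted p = 0.651), with Sulf1 at -0.21 and Corin at -0.46. Oligodendrocyte precursor markers had a median of 0.0084 over 9 genes and a mean of -0.10 (test direction down, camera adjusted p = 0.805), with Olig2 at -0.60 and Bcas1 at 0.32. Neural crest and Schwann cell precursor markers had a median of 0.044 over 13 genes (camera adjusted p = 0.689). Microglia and macrophage markers had a median of 0.020 over 4 genes (camera adjusted p = 0.953), with Cd68 at -0.15 and Csf1r at 0.17. Skeletal muscle genes had a median of 0.082 over 7 genes (camera adjusted p = 0.907), with Chrna1 at -0.34 and Tnnt1 at 0.12. Endoplasmic reticulum stress and ATF4 targets had a median of -0.00028 over 26 genes and a mean of 0.0070 (test direction up, camera adjusted p = 0.651), with Ddit4 at 0.13. Interferon response genes had a median of -0.0034 over 10 genes and a mean of 0.043 (test direction down, camera adjusted p = 0.953), with H2-K1 at 0.45 and Ifit2 at -0.21. Sex-linked genes had a median of 0.49 over 5 genes (camera adjusted p = 0.177), with Ddx3y at 0.60 and Uty at 0.49. Averaged per library, no list level passed an exact permutation test of 5 against 5 libraries with adjustment over the lists. The smallest adjusted p of these tests was 0.603.

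**Figure D3:**
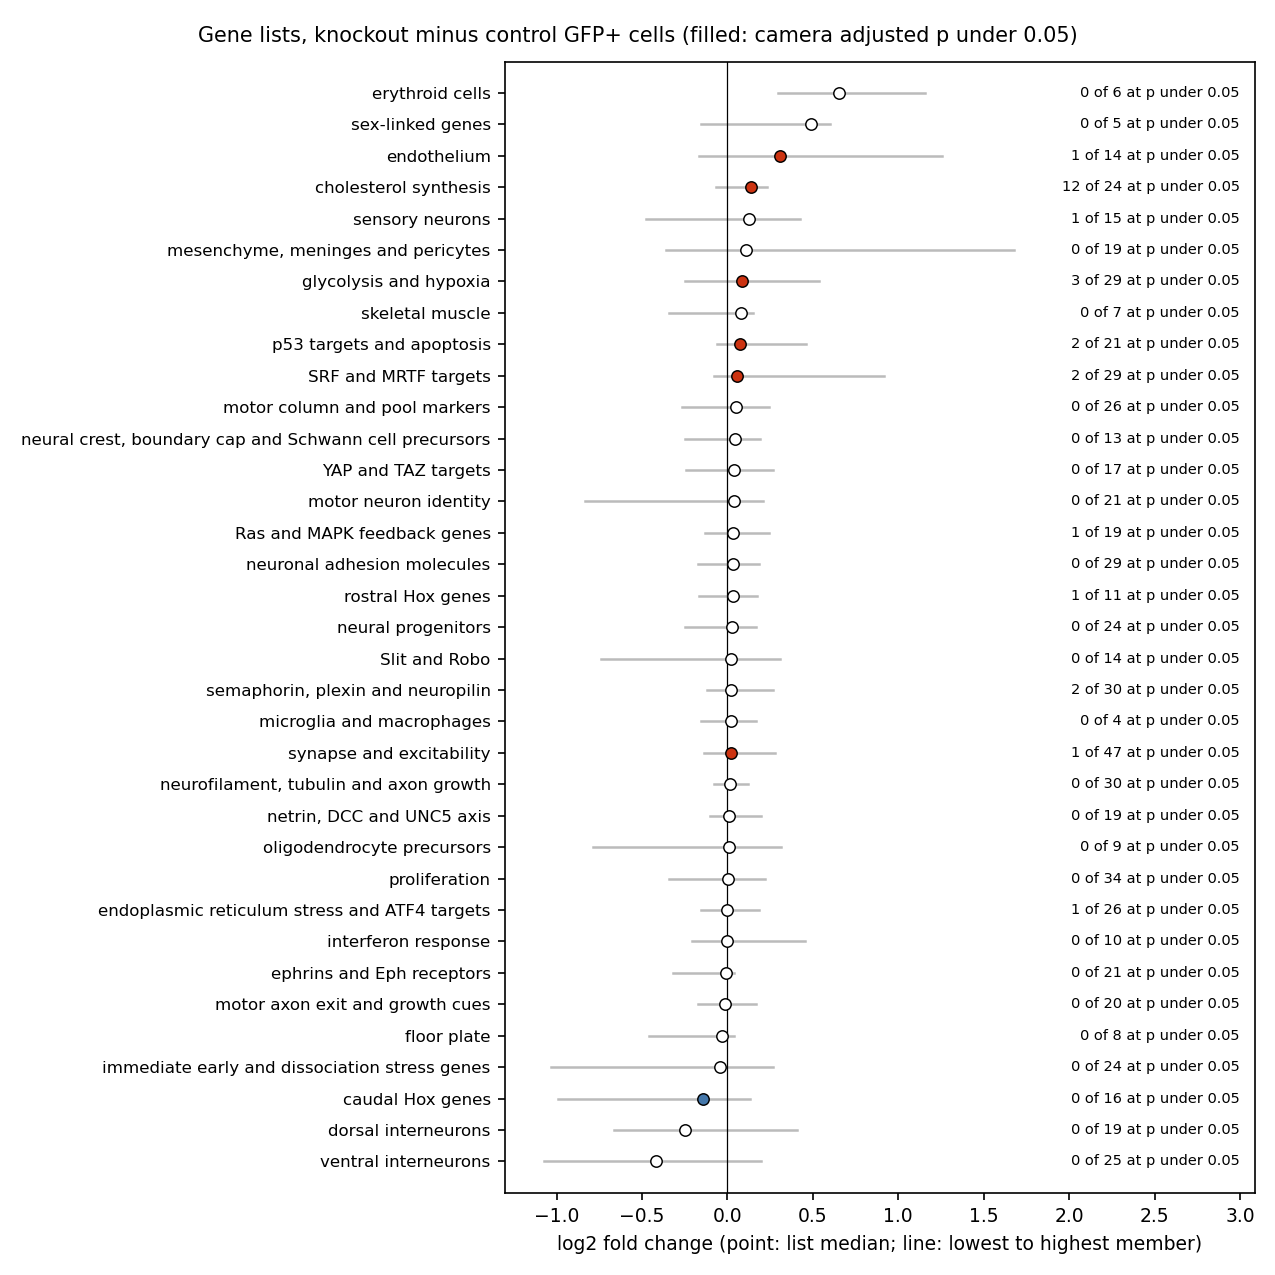
Gene lists compared between knockout and control GFP-positive cells (x axis, log2 fold change), with a point at the median of each list and a line from its lowest to its highest gene; filled points passed camera at its preset correlation, red for higher and blue for lower. The medians of called lists lie between -0.14 and 0.31, and the text at the right gives the number of genes with an unadjusted p under 0.05.

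The comparison of GFP-positive with GFP-negative cells, with genotype as a covariate, describes what the reporter sort separated. The largest rises in GFP-positive cells included motor neuron genes. Mnx1, the source of the reporter's promoter, stood at 253 ± 25.0 CPM in GFP-positive cells (SD, n = 10) and at 0.508 and 0.438 CPM in the GFP-negative libraries (log2 fold change 9.04, standard error 0.195, edgeR adjusted p = 7.68e-12). The motor neuron transcription factors Isl2 (8.43) and Irx6 (7.55), the intermediate filament Prph (7.13) and the neurotrophin Ntf3 (6.99) were among the largest log2 rises. Barx2, at 11.4 ± 1.28 CPM (SD, n = 10), had 0 counts in both GFP-negative libraries and was at least 216-fold higher, against a floor of 3 counts over both. By the same floor Slc17a4 was at least 59.5-fold, the peptide genes Uts2 at least 56.4-fold and Calcb at least 45.1-fold higher. Uts2b had 2 counts in the GFP-negative libraries, a ratio of 899.8 with a counting interval of 249 to 7429.9. Arhgap35 did not differ by this test (log2 fold change 0.082, edgeR adjusted p = 0.577).

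Dorsal genes were among those that led the other direction. Kirrel2 stood at 1.08 ± 1.00 CPM in GFP-positive cells (SD, n = 10) and at 65.5 and 62.0 CPM in the GFP-negative libraries (log2 fold change -5.89, standard error 0.663, edgeR adjusted p = 2.37e-05). Zic transcription factors followed, with log2 fold changes of -5.80 for Zic4, -5.49 for Zic1 and -5.37 for Zic2. Prdm13 (-5.69), the Wnt receptor Fzd10 (-5.47), Fgf15 (-5.34), Pax7 (-5.32) and the dorsal homeobox gene Msx3 (-5.29) were also among the 10 largest falls at an average log2 CPM of at least 1. Of 19763 genes tested, 5954 were higher and 6285 lower in GFP-positive cells by edgeR, 2454 and 2079 of them by more than 2-fold. With libraries scaled by their size only, 12285 genes were called, 11800 of them shared. Every GFP-positive library lay on the same side of both GFP-negative libraries for 60.7% of genes, where chance gives 3.03% if all 12 libraries are interchangeable. Both GFP-negative libraries carry replicate number 1, and the fit held no replicate term. Differences tied to that number were therefore not separated from those of the sort. Only 1 GFP-negative library per genotype was sequenced, so the spread of that group was taken from the model over all 12 libraries.

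Of 21 motor neuron identity genes 15 were higher and 3 lower (median log2 fold change 3.18, camera adjusted p = 8.32e-05; adjusted p = 0.325 with an estimated correlation). They included the cholinergic genes Slc18a3 (5.89) and Chat (6.26) and the guidance ligand Slit3 (4.27). Of 26 motor column and pool markers 19 were higher and 5 lower (median 1.94, camera adjusted p = 0.00263; adjusted p = 0.289 with an estimated correlation), among them Mecom (2.85), Nkx6-1 (2.22), Cdh7 (2.17) and Nr2f2 (1.72). Neurofilament, tubulin and axon growth genes were higher in 26 and lower in 3 of 30 cases (median 1.32, camera adjusted p = 1.40e-10; adjusted p = 0.289 with an estimated correlation). Nefm stood at 5419 ± 507 CPM in GFP-positive cells (SD, n = 10) against 203 and 208 CPM, Nefl had a log2 fold change of 4.29, and Gap43 2.79. Synapse and excitability genes were higher in 40 and lower in 3 of 47 cases (median 0.84, camera adjusted p = 1.12e-11; adjusted p = 0.289 with an estimated correlation), with Gria4 at 1.91, Syp at 1.53 and Cacna1b at 1.32. Neuronal adhesion molecules were higher in 23 and lower in 4 of 29 cases (median 1.32, camera adjusted p = 1.58e-06; adjusted p = 0.289 with an estimated correlation), with Cdh6 at 3.40, Itga3 at 1.98 and L1cam at 1.92.

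Cholesterol synthesis genes were higher in 14 and lower in 2 of 25 cases (median log2 fold change 0.46, camera adjusted p = 0.00286; adjusted p = 0.614 with an estimated correlation), with Sqle at 0.76. SRF and MRTF targets were higher in 12 and lower in 10 of 30 cases (median 0.027, mean -0.25, test direction up, camera adjusted p = 0.981), with Tpm1 at 1.42 and Lima1 at -2.16. YAP and TAZ targets were lower in 12 and higher in 4 of 19 cases (median -0.83, camera adjusted p = 0.0343; adjusted p = 0.289 with an estimated correlation), with Cyr61 at -2.46, Wwc1 at -1.44 and Tgfb2 at 2.75.

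Guidance families held genes higher in either population. Camera called none of these lists, while fry, which does not compare a list with other genes, called all 5 (adjusted p of 7.54e-08 to 0.0381). Semaphorins, plexins and neuropilins had 15 genes higher and 11 lower of 30 (median log2 fold change 0.24, camera adjusted p = 0.0628), with Sema3c at 4.50, Nrp1 at 2.79 and Nrp2 at 1.85. Slit and Robo genes had 7 higher and 5 lower of 14 (median 0.26, camera adjusted p = 0.166), with Slit2 at 3.18 and Nell2 at 1.22. The netrin, DCC and UNC5 list had 9 higher and 8 lower of 19 (median 0.011, camera adjusted p = 0.738), with Unc5c at 2.31 and Ntng1 at 2.09. Ephrins and Eph receptors had 9 higher and 9 lower of 22 (median 0.20, mean -0.21, test direction up, camera adjusted p = 0.956), with Epha10 at 1.79 and Epha2 at -3.69. Cues of motor axon exit and growth had 11 higher and 8 lower of 22 (median 0.10, camera adjusted p = 0.738), with the GDNF receptor Ret at 4.63, the HGF receptor Met at 2.60 and the chemokine receptor Ackr3 at -2.75.

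All 24 neural progenitor genes were lower in GFP-positive cells (median log2 fold change -4.02, camera adjusted p = 7.96e-12; adjusted p = 0.325 with an estimated correlation), among them Sox3 (-4.40), Dll1 (-2.79) and Vim (-1.33). All 34 proliferation genes were lower (median -3.51, camera adjusted p = 7.02e-16; adjusted p = 0.344 with an estimated correlation), with Rrm2 at -3.21 and Pcna at -1.69. Dorsal interneuron markers were lower in 25 of 26 cases (median -4.09, camera adjusted p = 5.90e-09; adjusted p = 0.344 with an estimated correlation), with Gsx2 at -6.37 and Ptf1a at -6.17. Ventral interneuron markers were lower in 21 and higher in 2 of 28 cases (median -3.14, camera adjusted p = 1.44e-05; adjusted p = 0.505 with an estimated correlation), with Sox21 at -4.67, Dbx1 at -4.54 and Gata3 at -3.96. Oligodendrocyte precursor markers were lower in 8 and higher in 2 of 11 cases (median -3.37, camera adjusted p = 0.0244; adjusted p = 0.424 with an estimated correlation), with Bcas1 at -4.96 and Cnp at 1.55. Rostral Hox genes were lower in all 11 cases (median -1.62, camera adjusted p = 4.90e-06; adjusted p = 0.344 with an estimated correlation), with Hoxa6 at -1.62 and Hoxa5 at -1.54. Caudal Hox genes went both ways, 9 higher and 5 lower of 19 (median 0.48, also with 2 genes absent from the GFP-negative libraries set to their bound, camera adjusted p = 0.738), from Hoxa11 at 3.46 to Hoxa9 at -1.62.

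Blood and connective tissue lists were lower in the GFP-positive population, and the endothelial list was not called by camera. Erythroid genes were lower in all 10 cases (median log2 fold change -3.81, camera adjusted p = 0.000240; adjusted p = 0.344 with an estimated correlation), with Hba-x at 1.60 ± 1.09 CPM in GFP-positive cells (SD, n = 10) against 25.6 and 38.3 CPM. Microglia and macrophage markers were lower in 11 of 12 cases (median -2.30, camera adjusted p = 0.00354; adjusted p = 0.424 with an estimated correlation), with Laptm5 at -2.68 and Csf1r at -2.56. Mesenchyme, meninges and pericyte genes were lower in 13 and higher in 4 of 21 cases (median -1.68, camera adjusted p = 0.0244; adjusted p = 0.579 with an estimated correlation), with Pdgfra at -3.37 but the collagen Col6a2 at 3.82. Endothelial genes were lower in 10 of 20 cases, 8 when adjusted over the list alone (median -1.07, camera adjusted p = 0.0639), with Robo4 at -3.03 and Sox18 at -2.75. Neural crest and Schwann cell precursor markers went both ways, 7 higher and 5 lower of 17 (median -0.34, mean -0.12, test direction up, camera adjusted p = 0.956), with Ngfr at 3.06. Sensory neuron markers did as well, 5 higher and 6 lower of 19 (median -0.14, camera adjusted p = 0.738), with Fxyd7 at 4.63, Isl1 at 3.56 and Prdm12 at -3.60. Skeletal muscle genes had 4 higher and 3 lower of 10 (median 0.12, mean -0.90, test direction down, camera adjusted p = 0.883), with Acta1 at 1.46 and Pax3 at -5.27. Floor plate markers had 2 higher and 5 lower of 11 (median -0.91, camera adjusted p = 0.610), with Ntn1 at -3.34 and Shh at 1.64.

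Lists of stress, glycolysis, growth signalling, interferon and sex-linked genes were not called by camera. Immediate early and dissociation stress genes had 14 higher and 3 lower of 24 (median log2 fold change 0.91, camera adjusted p = 0.0798), with Fosl2 at 3.80, Jun at 3.04 and Btg2 at -2.80. Glycolysis and hypoxia genes had 15 higher and 7 lower of 30 (median 0.43, camera adjusted p = 0.0869), with Pfkp at 3.63, Slc2a3 at 2.41 and Gpi1 at 1.92. The p53 and apoptosis list had 10 higher and 9 lower of 22 (median 0.23, camera adjusted p = 0.883), with the BH3-only gene Hrk at 4.99 and Ddit4l at -4.06. Endoplasmic reticulum stress and ATF4 targets had 11 higher and 10 lower of 26 (median -0.033, mean -0.026, test direction up, camera adjusted p = 0.956), with Asns at 2.26 and Phgdh at -3.90. Ras and MAPK feedback genes had 7 higher and 7 lower of 19 (median -0.099, camera adjusted p = 0.847), with Epha4 at 1.22 and Spred1 at -1.20. Interferon response genes had 3 higher of 14 (median 0.13, camera adjusted p = 0.759), among them Stat2 (0.51) and Ifi27, whose 3 counts in GFP-negative cells gave a ratio of 5.17 with a counting interval of 1.77 to 25.1. Of 6 sex-linked genes none was called (median -0.60, camera adjusted p = 0.847), with Kdm5d at -0.90. Most named log2 fold changes kept their call under every alternative. Among those that did not, Ifi27 lost it in knockout libraries alone and without the control GFP-negative library, Emcn in control libraries alone and without the knockout GFP-negative library, and Stat2 without the control GFP-negative library.

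**Figure D4:**
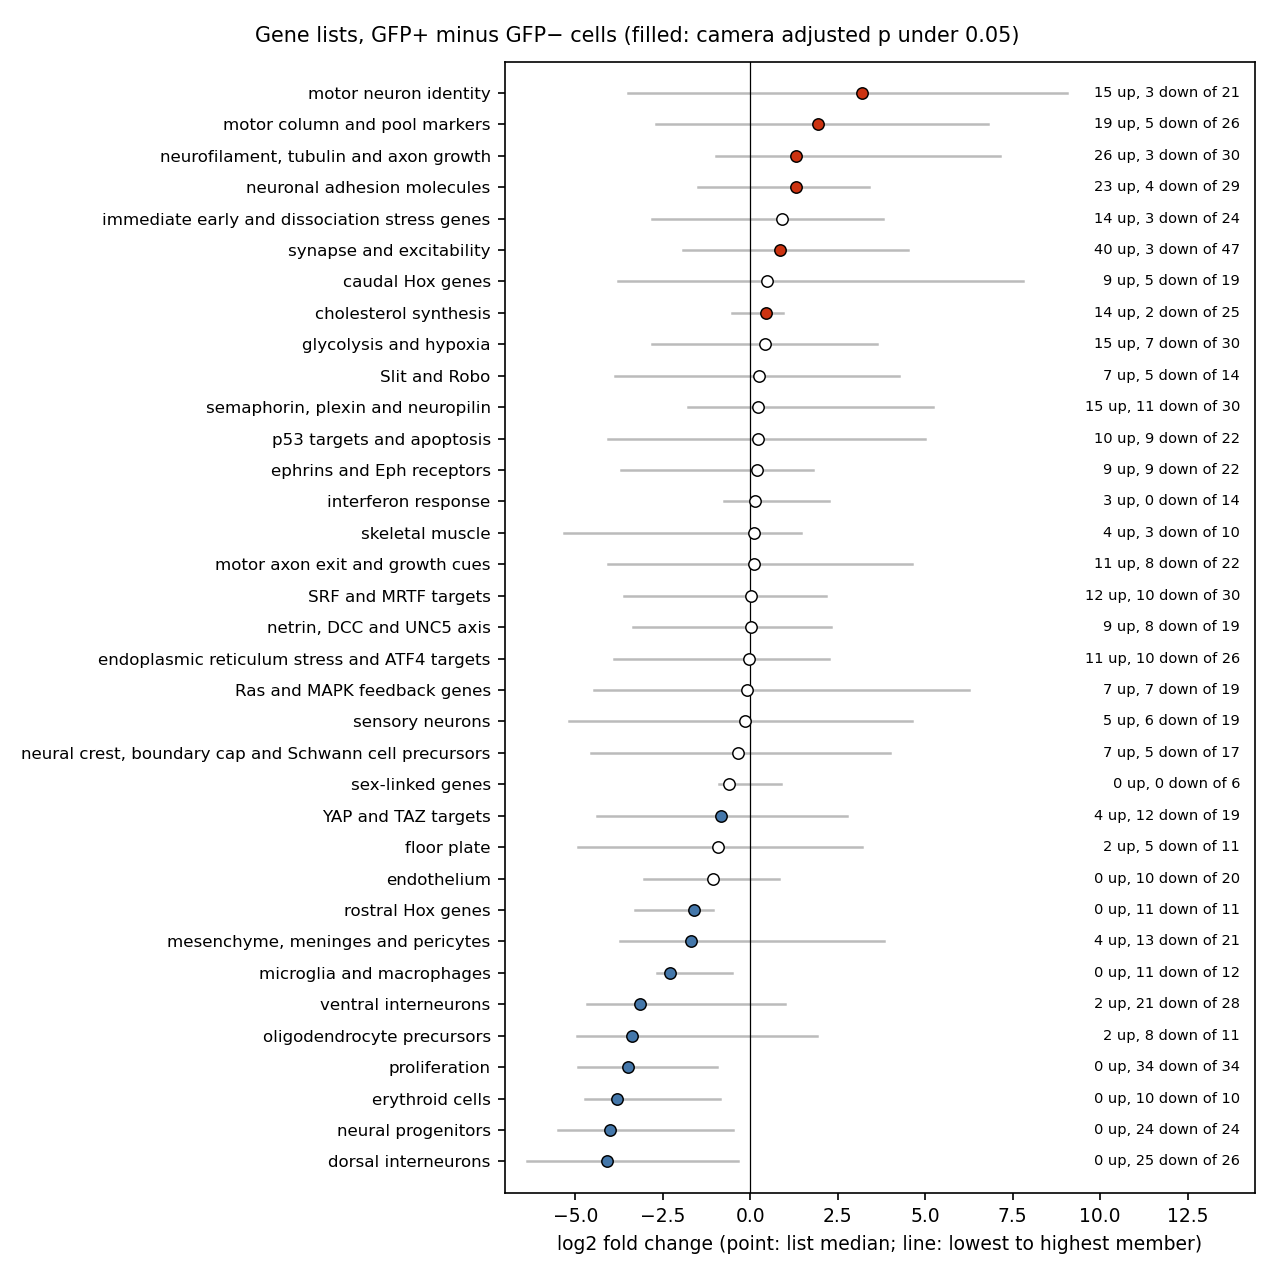
Gene lists compared between GFP-positive and GFP-negative cells (x axis, log2 fold change), with a point at the median of each list and a line from its lowest to its highest gene as fitted; filled points passed camera at its preset correlation, red for higher and blue for lower. Motor neuron identity has the highest median, 3.18, and dorsal interneurons the lowest, -4.09; the text at the right counts called genes.

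Whether the knockout acted alike in both populations was tested as the difference of its effect between GFP-negative and GFP-positive cells. By edgeR 2 genes were higher and 3 lower, all 5 of them unnamed gene models with 0 counts in 1 of the GFP-negative libraries. AK166824 (0 counts in the control and 24 in the knockout library, log2 difference 7.67) and Gm13414 (0 and 124, log2 difference 9.67) were higher, with edgeR adjusted p of 0.0166 each. B930095G15Rik (5.15 CPM in the control and 0 in the knockout library, log2 difference -10.14, adjusted p = 0.0166), Gm4750 (76 counts and 0, log2 difference -9.58, adjusted p = 0.0280) and AK089373 (27 counts and 0, log2 difference -8.03, adjusted p = 0.0436) were lower by the same test. These fitted differences depend on edgeR's default prior count and are no bounds. Voom called 0 genes (339 at an unadjusted p under 0.05, against 352 by edgeR) and DESeq2 2 others. Without control GFP-positive replicate 5 edgeR called 0, without control replicates 1 and 2 it called 2 and 1 of the 5, and without knockout replicates 1 and 3 or control replicate 4 it called 3 of them. In GFP-positive cells the 5 genes stood between 1.69 and 7.05 CPM on average in each genotype. Among named genes the smallest p-values belonged to Gpr12 (log2 difference -1.13), Diap1 (1.08) and Emc8-1190005i06rik (-3.81), which were not called (edgeR adjusted p = 0.99997 each). In the GFP-negative pair, without replicates, Diap1 stood at 25.5 CPM in the control and 53.6 CPM in the knockout library, Ercc2 at 74.5 and 57.4 CPM, Ccdc61 at 12.1 and 10.6 CPM and Gipr at 2.14 and 3.80 CPM.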

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

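The test of neighbours within a short distance of Arhgap35 and the splits for the genes near it were chosen only after the result was seen. In groups of 5 libraries a library was singled out when it lay far from the other 4 by Dixon's criterion, and chance flags about 1 in 20 groups. Of 240 groups tested, 17 held such a library (7.08%).

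In control GFP-positive cells, replicate 1 had the largest total (30.2 M estimated counts, others 23.7 to 24.2) and the most genes detected (24630, others 24098 to 24244). Its level of Hoxd9 was also high (39.9 CPM, others 30.4 to 32.0). Control replicate 4 stood out for Cdon (38.3 CPM, others 30.8 to 32.0), for Tbx20 (2.34 CPM, others 0.378 to 0.596) and for a low erythroid list level (-1.22 mean log2 CPM, others -0.29 to -0.029).

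In knockout GFP-positive cells, replicate 3 stood out most often. Its Y-linked genes were low, with Ddx3y at 0.163 CPM (others 19.9 to 23.6) and Uty at 1.18 CPM (others 11.1 to 12.9), and so was its level of the sex-linked list (0.978 mean log2 CPM, others 4.11 to 4.22). Control replicates 4 and 5 were lower still for this list (0.464 and 0.256, other control libraries 3.66 to 4.31), so such libraries occur in both genotypes. The same library had high Cdh20 (19.96 CPM, others 16.8 to 17.7), Spry2 (15.1 CPM, others 11.2 to 12.3) and semaphorin, plexin and neuropilin genes (6.32 mean log2 CPM, others 6.19 to 6.21), and low microglia and macrophage genes (-1.89, others -1.16 to -0.89). Replicate 2 had low Cntfr (163 CPM, others 171 to 173) and high Ntn3 (21.1 CPM, others 17.3 to 18.2). Replicate 4 had high Tbx20 (1.07 CPM, others 0.245 to 0.410), and replicate 1 had no Grlf1 (0 CPM, others 7.15 to 8.34). The cause was not tested for any of these.

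By edgeR, 5 unnamed gene models differed between the populations in their response to the knockout. The log2 difference (GFP-negative minus GFP-positive) was 7.67 for AK166824, 9.67 for Gm13414, -10.14 for B930095G15Rik, -9.58 for Gm4750 and -8.03 for AK089373. Each has 0 counts in 1 GFP-negative library and more than 20 in the other, so each rests on a single library. How reads were assigned to these models could not be examined from gene-level tables.

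The first pattern weighed is the 6 genes called between knockout and control GFP-positive cells. Called genes were more frequent within 20 Mb of Arhgap35 (4 of 407, against 1 of 15560 elsewhere; one-sided Fisher's exact test, p = 2.04e-06), as linked strain variants around the targeted locus would give; a biological response of these genes to the loss of Arhgap35 stays open. Fisher's test counts genes of the same 10 libraries as separate units. Of 100 splits of the 10 libraries, 6 gave as many genes as the real split (6 genes, highest other 194), so chance is not excluded over all splits. The splits with many genes, up to 194, keep most libraries of the same replicate number together, which points to structure by replicate. Among the 11 splits that part all 5 pairs, as the real split does, the highest other called 0.

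The second pattern is the 7 gene lists called with camera at its preset correlation. Of the 100 splits 68 called as many lists (real split 7, highest other 17), so chance is not excluded, and among the 11 splits that part all 5 pairs 3 did (highest other 9). An effect of the genotype on these lists stays open.

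The third pattern is the set of differing genes near Arhgap35, measured as the odds ratio of an unadjusted p under 0.01 within 20 Mb against elsewhere. Only the real split, 1 of 100, reached its value (42.6, highest other 11.5). It was also the only 1 among the 11 splits that part all 5 pairs (highest other 5.46). As 11 such splits cannot give less than 1 in 11, they do not exclude chance. The number of near genes with such a p was 31 in the real split. Other splits reached up to 27, and those that part all 5 pairs up to 1. The farthest called gene on the chromosome, Ercc2, lies 2.77 Mb away, which argues against an effect on immediate neighbours alone. Near genes were also chosen by an unadjusted p under 0.01 in GFP-positive replicates 2 to 5 alone and at least 10 counts over the GFP-negative pair. In the GFP-negative pair 76% of them (19 of 25, confidence interval 54.9 to 90.6%) differed in the same direction, against 54.8% of 42 genes chosen likewise elsewhere (Fisher's exact test, p = 0.118). That share lies between the limits set beforehand, so linked strain variants, a local effect of the allele and a response of motor neurons alone cannot be told apart with 1 GFP-negative library per genotype.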

How the results depend on the processing

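Leaving out genes within 20 Mb of Arhgap35 with the replicate block, or from the lists, and summing Arhgap35 with Grlf1 were chosen only after the results were seen. The cause was not tested where none is given.

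Between knockout and control GFP-positive cells edgeR called 1 gene higher and 5 lower, and other scaling, no filter and voom gave 1 higher and 4 or 5 lower. It called 0 higher with a CPM of at least 1 in 5 libraries, robust fitting off, all 12 libraries or 1 surrogate variable, with 4 or 5 lower in each. DESeq2 called 5 higher and 9 lower, the replicate block 2 higher and 3 lower. Limma on log2 TPM called 0 higher and 0 lower with either pseudocount or no filter (444 to 996 at an unadjusted p under 0.05). Without genes within 20 Mb of Arhgap35 edgeR called 0 higher and 0 lower (310 at an unadjusted p under 0.05), where 5 of the 6 genes are removed and Akt2-ps missed the threshold, and with the block as well 1 higher and 0 lower. Leaving out 1 library gave 0 to 2 higher and 0 to 6 lower.

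Arhgap35 stayed lower throughout but missed the threshold with no filter (log2 fold change -0.84), limma on log2 TPM with pseudocount 1 (-0.79, adjusted p = 0.0565), with 0.1 (-0.81, 0.0539) and with no filter (-0.79, 0.133), the replicate block (-0.82, 0.162) and 1 surrogate variable (-0.83, 0.0992). Over all alternatives its adjusted p ran from 8.18e-13 to 0.162. Leaving out 1 library gave -0.91 to -0.77.

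GFP-positive against GFP-negative counts stayed within 1.5 times under every alternative (8948 to 12404 called). The interaction (2 higher, 3 lower) became 1 and 1 with DESeq2, 0 and 0 with voom, and 0 to 4 higher and 0 to 3 lower without 1 library.

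Of the lists between the genotypes, 6 higher and 1 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry, 11 and 4 with the replicate block, 10 and 2 with 1 surrogate variable, 7 and 1 without genes within 20 Mb, and 5 to 10 higher and 1 to 3 lower without 1 library. The synapse list reversed without control replicate 1 (adjusted p = 0.816, others 2.26e-05 to 0.234). Of the lists between the populations, 7 higher and 10 lower became 0 and 0 with an estimated correlation and 15 and 18 with fry.

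Of the single-gene and single-list values, 5479 kept their side of the threshold, 139 lost a call and 1 reversed. Values called in neither fit counted as kept whatever their direction, so these counts do not show that direction was kept. In simulated data with these depths small fold changes were recovered less often than large ones, and at 3 counts the floor is 0.0887 to 0.127 CPM.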

Other observations

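No test in this part was chosen after results were seen, but the genes near Arhgap35 were. Some receptors and ligands of growing motor axons were higher in GFP-positive cells, while the lists of such genes held genes changed in either direction and were called by fry but not by camera. These genes were picked from among called members of the lists. The neurotrophin receptor Ngfr stood at 754 ± 58.6 CPM (SD, n = 10) against 96.3 and 84.3 CPM in the control and knockout GFP-negative libraries, Ret at 404 ± 39.5 against 16.1 and 16.5 CPM, and Met at 83.6 ± 4.07 against 14.4 and 13.1 CPM. The repellent Slit2 stood at 900.3 ± 89.8 against 99.1 and 99.2 CPM, Sema3c at 359 ± 26.8 against 15.5 and 16.1 CPM, and Nrp1 at 394 ± 30.3 against 55.8 and 58.1 CPM (SD, n = 10). Hrk, a BH3-only gene of neuronal death, stood at 121 ± 17.6 against 3.25 and 4.42 CPM, and Jun at 268 ± 19.2 against 30.3 and 35.2 CPM (SD, n = 10).

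In the GFP-negative pair, 1 library per genotype, several neighbours of Arhgap35 differed in the same direction as in GFP-positive cells. The log2 ratio of knockout to control was -1.12 for 9330104G04Rik, 0.41 for Tmem160, 0.29 for Pnmal1, -0.44 for Npas1 and -0.20 for Mark4. It was opposite for Bcam (-0.30, against 0.47 in GFP-positive cells), Klc3 (-0.34, against 0.76) and Slc1a5 (-0.69, against 0.30). The same held for Blvrb (0.21, against -0.48), Inafm1 (-0.035, against 4.75) and Nova2 (-0.068, against 0.16). Klc3, Inafm1 and Npas1 stood below 1 CPM in both GFP-negative libraries, so their directions there are uncertain.

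Levels of blood and vessel markers varied between libraries of the same genotype. The erythroid list stood at -0.387 ± 0.475 mean log2 CPM in control and -0.109 ± 1.01 in knockout GFP-positive cells (SD, n = 5 each; exact permutation p = 0.563), and at 3.11 and 3.67 in the control and knockout GFP-negative libraries. The endothelial list stood at -0.876 ± 0.334 and -0.493 ± 0.472 (SD, n = 5 each; exact permutation p = 0.175), and at 0.116 and 0.428 in the GFP-negative libraries.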
